A study of Mus musculus with 6 samples.

How the data were processed

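Gene expression was measured with CEL-seq2 in single cells of Dach1 reporter mice, which the labels call hematopoietic stem and progenitor cells. Per the labels' protocols, one cell was sorted per well of 384-well plates with primers and ERCC spike-ins. Wells were pooled after first strand synthesis, so each plate is one library. Per the labels, read 1 starts with a cell barcode of 8 bases followed by a molecular identifier of 6 bases. For each plate the submitters deposited a table of gene counts by well, in which every value was a whole number and is taken as a count of UMIs. The aligner and the counting program are not given in the sources used here. The submitters' processing notes name the human build GRCh38, whereas the identifiers in the tables are mouse Ensembl genes, so the build behind the counts is not settled. Coordinates come from the GENCODE M21 annotation of GRCm38 and describe the annotation, not the counting. Symbols were found for 25706 of 25770 gene identifiers in a table of mouse gene names.

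The 6 plates carry one description, so they form a single group with plates as replicates 1 to 6, and no plate or well was assigned a genotype. Each table held 383 wells and no spike-in rows, so no spike-in share could be given. A well was kept with at least 1000 UMIs, at least 500 genes and under 20% of UMIs from mitochondrial genes. The last limit alone removed no well. Of the left-out wells, 45 had the same position in every plate, and the barcode annotation, which maps no well to a genotype, was not used. No doublet caller was run, since each well was sorted as a single cell. The lowest chi-square per degree of freedom between the totals of any plates was 5.3, so no plate was a copy of another. Levels per plate are CPM over the UMIs of kept wells with exact Poisson intervals, and shares of wells have exact Clopper-Pearson intervals, all at 95%. A count of 0 was given a limit of 3 counts. For shares of cells with a UMI of Bcor or Dach1, each cell of at least 5000 UMIs was also thinned to that depth, which left 1531 cells and dropped 487.

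Genes were split by a hash of their identifier into a clustering set of 12760 genes, which holds all cell type markers, and a test set of 13010 genes, which holds all genes of the tested lists. Clustering used scanpy 1.11.5 and igraph 0.11.9 with the 1000 most variable genes of the clustering set, counts scaled to 10000 per cell and log-transformed, 20 principal components, 15 neighbours and Leiden resolution 1. A cluster was named after the marker list with the most genes among its top 10 genes by fold, or among tied lists the one with more raised markers, if at least 3 of the list's markers were raised, that is at least 2-fold higher than in the other cells and seen in at least 5% of the cluster. The fold used an offset of 10 CPM and top genes needed 50 CPM. The 13 marker lists covered stem, megakaryocyte, erythroid, myeloid-primed, lymphoid-primed, B, dendritic, monocyte-macrophage, neutrophil, T and NK, mast and basophil, eosinophil and stromal cells. Cluster 0 was such a tie, between the dendritic and the lymphoid-primed list.

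For each comparison, counts were summed per plate over the cells of the cluster and over all other kept cells, in plates with at least 10 cells on each side and in at least 3 plates. The sums were tested with edgeR 4.0.16 (quasi-likelihood fit, TMM scaling, low-count filter, plate as block) in R 4.3.3, with Benjamini-Hochberg adjustment over the test set genes that passed the filter and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of its F value. The 17 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, for lists with at least 5 tested genes. Fry, a planned test that does not set a list against the other genes, was run on the same lists. Genes named with values follow a rule: per comparison, among genes past the threshold with at least 50 CPM on the higher side and the same direction in every plate, the 10 with the largest change each way, then up to 3 members of each list with the smallest adjusted p, and Bcor, Dach1 and Irf8. The text names a selection of these. The wells' limits, clustering, markers, lists, tests, the rule for named genes and most of the other settings were fixed before the data were examined. The numeric limits for naming and matching clusters were set later.

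The sums of a plate come from one library, and their deviations from the side means correlated at 0.121 to 0.507 in every plate and comparison, so the plate pairs them. The test was tried on simulated data with the real library sizes, the means of each plate's rest sum and 200 genes changed. One fixed dispersion, not the data's own, served for every gene, and only genes above a minimum mean count were changed. Recovery and false calls in the real comparisons may therefore differ. In the cluster 0 design (4970 genes) it recovered 54% of 2-fold and 88% of 4-fold changes, in the cluster 7 design (5125 genes) 23% and 78%, and in the cluster 9 design (5023 genes) 15% and 78%. Over the 10 designs of a cluster against the rest, the share of false calls was 1.75 to 5% and 100% of recovered genes had the right direction. Kept wells had between 1033 and 39215 UMIs.

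The alternatives were no plate block, RLE size factors, DESeq2 1.42.0, no low-count filter, each plate left out in turn, cells thinned to 5000 UMIs before summing, resolutions 0.6 and 1.5, clustering on values centred within each plate, and well limits of 500 UMIs with 250 genes or 2000 UMIs with 1000 genes. Clusters of an alternative were matched to the original ones by an overlap (Jaccard index) of at least 0.5. Leaving out plates 5 and 6 together was added after the data were seen, as were the comparisons of the unnamed clusters and of cluster 0 with cluster 6. The planned comparison of cells with and without a Dach1 UMI was not run, because no plate had 10 thinned cells with one. The planned comparison of lymphoid-primed with myeloid-primed cells was not run, because no cluster was named myeloid-primed-like. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.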

Results

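Single cells from the bone marrow of Dach1 reporter mice, labelled as stem and progenitor cells, were sequenced one cell per well with CEL-seq2. This 3′ method tags each cDNA molecule with a unique molecular identifier (UMI). The labels call the cells LSK, the usual name of the lineage-negative Sca1-positive c-Kit-positive marrow fraction that holds stem cells and multipotent progenitors. Their protocols also describe culture with Flt3 ligand, a cytokine of dendritic cell development, without saying whether the sequenced cells went through it. Dendritic cell and neutrophil markers named some of the clusters described below and no cluster was stem-like, so the label may not describe every sequenced cell. The series has 6 samples, each the library of one 384-well plate, and all 6 carry the same description, HSPCs with and without Bcor knockout. No label says which plates or wells held knockout cells, so the plates form a single group, LSK, with replicates 1 to 6, and no comparison by genotype was made. Each file held 383 wells, and between 334 and 338 wells per plate passed the quality limits, 2018 in all. Total UMIs over all wells were 2443394, 4702338, 2908497, 4505258, 2268303 and 2429104 in plates 1 to 6. The median depth per kept well was 6286, 12414, 7337, 11249, 5507 and 6079.5 UMIs, over medians of 2420, 3584, 2691, 3636, 1866 and 2376.5 genes. Levels are given as CPM, UMIs scaled to a common total over the kept wells, and every interval and floor covers counting error only.

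Bcor, the corepressor named in the study's title, is the targeted gene (ENSMUSG00000040363, chromosome X, 12036740 to 12160355, minus strand, in the GRCm38 annotation). Its level was 64.9 (95% interval 55.1 to 75.8) CPM in plate 1 and 38.2 (95% interval 32.8 to 44.2) CPM in plate 2, with exact Poisson bounds. Plates 3 and 4 held 48.9 (95% interval 41.2 to 57.7) and 61.9 (95% interval 54.8 to 69.6) CPM. In plates 5 and 6 the level was 25.2 (95% interval 19.1 to 32.7) and 17.4 (95% interval 12.5 to 23.5) CPM. The intervals of plates 1 and 6 did not overlap, and the labels give the plates no contrast. A Bcor UMI was seen in 26.3, 35.5, 26.9, 46.9, 9.85 and 8.93% of kept wells in plates 1 to 6. In the cells of at least 5000 UMIs, thinned to that depth, the shares were 19.6, 18.4, 18.1, 27.9, 8.7 and 9.38%. These cells numbered 219, 321, 254, 297, 184 and 256 in plates 1 to 6. Shallower cells were dropped, so the shares cover another set of cells than those of all kept wells. The position of the edit in Bcor is not given, and a 3′ count can stay unchanged by an edit elsewhere in the gene, so these levels check no knockout label.

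Dach1, the gene of the reporter (ENSMUSG00000055639, chromosome 14, 97786853 to 98169765, minus strand), lay near the floor of the data, with 12 UMIs in all. A Dach1 UMI was seen in 10 of 2018 cells, 0.496% (exact 95% interval 0.238 to 0.909%). In the cells thinned to 5000 UMIs it was seen in 3 of 1531, 0.196% (0.0404 to 0.572%). Plate 2 had 0 of 338 cells, for which the limit of 3 counts corresponds to 0.888% of cells with a UMI. That limit is not the bound of an exact 95% interval. Cells with and without Dach1 transcripts could therefore not be compared. Irf8, a transcription factor of dendritic cell and monocyte development (ENSMUSG00000041515, chromosome 8, 120736358 to 120756694, plus strand), was abundant, at 944.5, 748, 832, 856.5, 1717 and 1387 CPM in plates 1 to 6. Ly6a, which encodes Sca1, stood at 844, 639, 735.5, 716, 1814 and 1754 CPM in the same order. Flt3, the receptor for the cytokine that drives dendritic cell development, stood at 208.5, 158, 261, 223, 122.5 and 164 CPM. Kit was measured at 42.3, 23.7, 54.1, 45.4, 42 and 80.6 CPM. Siglech, a marker of plasmacytoid dendritic cells, had 48, 36, 58.3, 48.7, 555 and 744 CPM, and Xcr1, a marker of type 1 conventional dendritic cells, 12.7, 10.9, 14.1, 2.67, 65.9 and 103 CPM.

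**Figure D1:**
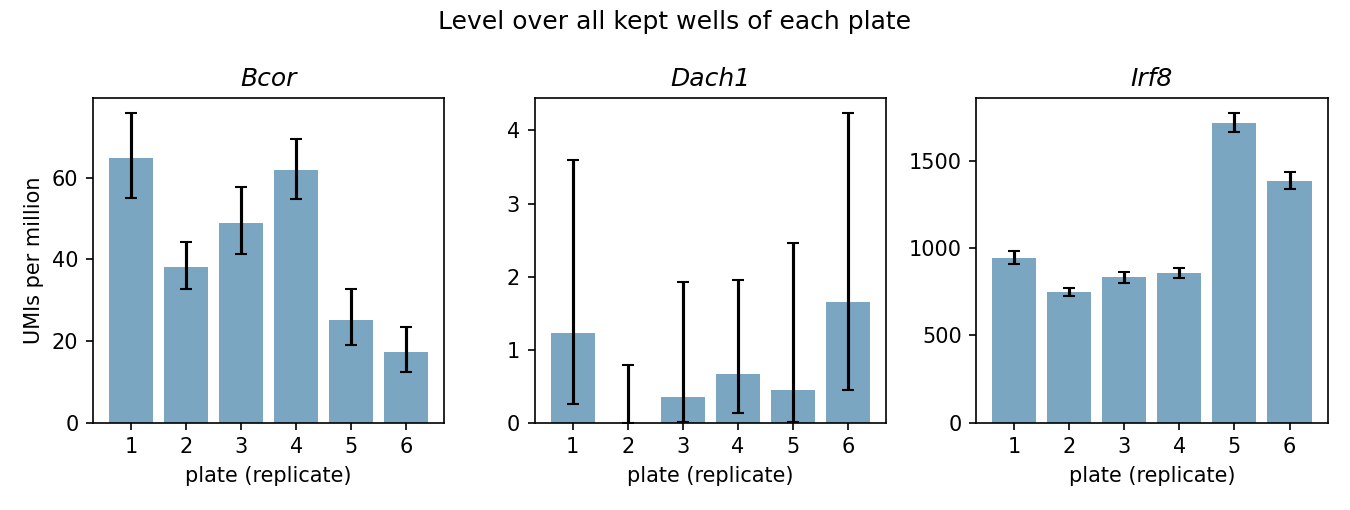
Bars give the level of Bcor, Dach1 and Irf8 in CPM over the kept wells of each of the 6 plates, and error bars the exact Poisson 95% interval. Bcor ranged from 17.4 to 64.9, Dach1 from 0 to 1.65 and Irf8 from 748 to 1717 CPM.

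The kept cells fell into 11 Leiden clusters, and markers fixed in advance named 3 of them. Cluster 0 (399 cells) was dendritic-cell-like, with 6 dendritic cell markers raised at least 2-fold and Siglech, Ctsl, Pacsin1 and Ccr9 among its top genes. In it 4 lymphoid-primed markers were raised too, and on values centred within each plate the matched cluster had no name. Its share of the kept wells was 11.7, 8.88, 15.4, 14.8, 34.9 and 33% in plates 1 to 6. The matched cluster took 0.898, 0, 5.62 and 1.78% of plates 1 to 4 at resolution 1.5, 1.19, 0, 3.24 and 0.292% under the looser well limits and 1.53, 0, 4.83 and 1.81% under the stricter ones, and in plates 5 and 6 33.1 and 31.8%, 35.2 and 31.9% and 37 and 33.1%. Cluster 7 (104 cells) was lymphoid-primed-like, with 7 raised markers and Rag1, Rag2, Dntt, Il7r and Ly6d on top, and took 3.29, 3.55, 9.17, 9.5, 3.58 and 1.79%. On centred values the matched cluster (overlap 0.51) took 5.09, 5.62, 6.8, 6.82, 3.58 and 5.36%, so these plate differences depend on the clustering. Cluster 9 (89 cells) was neutrophil-like, with S100a8, S100a9, Ngp, Camp and Lcn2 on top, and took 2.99, 3.85, 2.66, 1.78, 8.06 and 7.14%. It also had 9 myeloid-primed and 7 monocyte and macrophage markers raised, and the matched cluster was myeloid-primed-like at resolution 1.5 and on centred values. All 8 neutrophil markers were raised in cluster 9 over all plates together, yet its 10 wells in plate 1 held 6 UMIs of them. Per well of cluster 9, these markers came to 0.6, 19.5, 127, 53, 234 and 129.6 UMIs in plates 1 to 6.

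The other clusters are given by number with their top genes. Cluster 1 (324 cells) had Id2, Ccr1, Klf4 and Ciita on top, with shares of 24, 29.3, 20.7, 16.6, 2.09 and 3.57% in plates 1 to 6. The matched cluster took 17 and 23.8% of plates 5 and 6 on centred values and 17 and 30.7% at resolution 0.6, so the low shares of these plates depend on the clustering. Cluster 2 (308 cells) had Snhg3, Myc, Ung and Cdca7, with 24.3, 25.7, 14.8, 23.1, 2.39 and 1.19%, and 8.06 and 5.06% of plates 5 and 6 on centred values. Clusters 3 (283 cells) and 8 (100 cells) had histone H2A genes on top, with 22.2, 15.1, 18, 17.8, 6.57 and 4.46% and with 6.29, 8.88, 1.48, 6.53, 3.88 and 2.68%. The cluster matched to cluster 8 took 4.44 and 5.95% of plates 3 and 6 on centred values. Its share of plate 3 was 5.14% under the stricter well limits and stayed at 1.48% at resolution 1.5. Cluster 4 (164 cells) had Gzmc, Xcl1, Itgam and Clec10a, and its shares were 1.5, 0.592, 4.14, 0.89, 16.1 and 25.6%. On centred values and at resolution 0.6 no cluster matched it, and its largest overlap, 0.271 and 0.286, was with the cluster matched to cluster 1. Cluster 5 (125 cells) had Ccl5, Ccr7, Ccl22 and Fscn1, and its shares were 0.898, 0.888, 8.88, 6.82, 10.4 and 9.23%. Cluster 6 (117 cells) had Naaa, Xcr1, Itgae and Tlr3, and its shares were 2.99, 2.96, 4.14, 1.78, 11.9 and 11%. Cluster 10 held 5 wells with small nuclear and other short RNAs on top. No cluster was stem-like, megakaryocyte-like or erythroid-like, and none was myeloid-primed-like at the settings used, so the lymphoid-primed against myeloid-primed comparison had no cells to run on. Cells of clusters 3 and 8 had median depths of 14700 and 12489 UMIs, against 5025 in cluster 0.

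**Figure D2:**
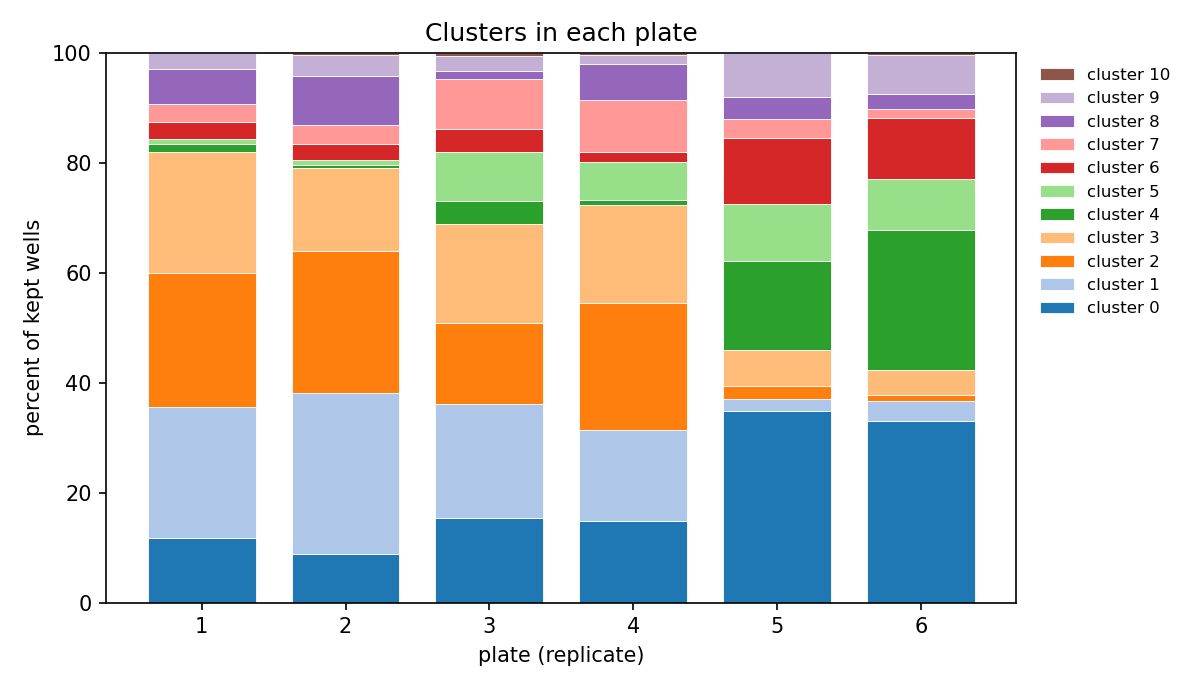
Stacked bars give the percent of kept wells in each cluster (legend) for the 6 plates. Cluster 0 ranged from 8.88% in plate 2 to 34.9% in plate 5, cluster 4 from 0.592% in plate 2 to 25.6% in plate 6, and cluster 2 from 1.19% in plate 6 to 25.7% in plate 2.

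Each cluster was compared with all other kept cells of the same plates, which asks which genes of the test set differ in that cluster. Histone H2A genes of the test set are not named, because near-identical copies were used for the clustering and the copies followed each other across cells (r of 0.911 to 0.976), so their changes partly restate the clusters. Lyz1 is left out because its paralog Lyz2 was in the clustering set, and the counts of genes called include all of these. The comparisons of clusters 0, 7 and 9 were planned, and those of the unnamed clusters and of cluster 0 with cluster 6 were chosen after the clusters were seen. Fold changes are log2 ratios from edgeR's quasi-likelihood test with plate as a block and Benjamini-Hochberg adjusted p over the genes tested. With the block, the p-values set a change against how the difference between cluster and rest varied from plate to plate, which may be technical. They hold only given the clusters found in the same cells. List tests used camera with a preset correlation. With an estimated correlation, 5 lists held in cluster 2 and 6 in cluster 3, and none in the other 9 comparisons, where the lowest adjusted p was 0.064. Members of a list that are named without a value were chosen after their values were seen. Bcor itself passed in no comparison, with adjusted p from 0.0518 in cluster 0 to 0.997 in cluster 6.

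Tcf4 and Irf8 were high in cluster 0. Tcf4, the E protein that sets plasmacytoid dendritic cell identity (ENSMUSG00000053477, chromosome 18, 69343356 to 69689079, plus strand), stood at 1778 ± 407 CPM against 348 ± 57.2 CPM in the other cells (SD, n = 6 plates; log2 fold change 2.29, SE 0.09, adjusted p = 2.59e-19), higher in 6 of 6 plates. Irf8 stood at 2661 ± 682.5 against 810.5 ± 157.5 CPM (log2 fold change 1.66, SE 0.07, adjusted p = 2.59e-19), likewise higher in 6 of 6. Spib, Runx2, Bcl11a and Zeb2, further factors of this lineage, were higher by 2.76, 1.95, 1.38 and 0.87. Among genes with the largest changes, Hsd11b1 rose by 4.18, Pacsin1 by 3.41 and Blnk, a B-cell receptor adaptor, by 2.72.

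Of 17 tested dendritic cell fate factors, 8 were higher and 6 lower in cluster 0, the same 8 higher and 6 lower adjusted over the list alone (camera adjusted p = 8.25e-10, and adjusted p = 0.0911 with an estimated correlation). The lower ones were Spi1 (-0.71), the factor PU.1, and Id2, Batf3, Relb, Klf4 and Zfp366, of which Id2 and Batf3 belong to conventional dendritic cells. Lymphoid factors rose in 6 of 10, among them Notch1 (1.42) and Foxo1 (1.21), and 1, Tcf3, fell, with 6 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00335, and adjusted p = 0.0911 with an estimated correlation). Of 23 interferon response genes, 9 were higher, such as Stat1 (1.18), Ly6a (1.22) and Ifi27l2a (0.85), and Ifit1 and Ifi27 were lower, with 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 9.16e-05, and adjusted p = 0.163 with an estimated correlation). Cytokine receptors went both ways, 7 of 20 higher and 5 lower, with 7 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.15). The receptors of type I interferon, Ifnar1 and Ifnar2, were higher by 2.04 and 0.96, as was Csf2rb2 by 1.39, and Kit, Csf2ra, Il1r1, Il6st and Ifngr1 were lower. In the myeloid list, 4 of 10 were higher (Irf8, Klf2, Hhex and Zeb2) and Spi1 and Klf4 lower, with 4 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0191, and adjusted p = 0.163 with an estimated correlation). The median of that list was -0.12 and its mean 0.15, so they differ in sign.

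Antigen presentation and growth genes were lower in cluster 0. MHC class II genes fell in 7 of 12, among them the invariant chain Cd74 (-0.87), H2-Aa (-0.73) and H2-Ab1 (-0.51), and 1, the protease gene Ctss, rose, with 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.00234, and adjusted p = 0.442 with an estimated correlation). G2/M genes fell in 31 of 52 (0 higher and 34 lower adjusted over the list alone; adjusted p = 0.171 with an estimated correlation), including Hmgb2 (-1.29) and the topoisomerase Top2a (-0.60). S phase genes fell in 21 of 42 (0 higher and 26 lower adjusted over the list alone; adjusted p = 0.106 with an estimated correlation), with Pcna at -0.63. Ribosomal protein genes fell in 30 of 37 (1 higher and 30 lower adjusted over the list alone; adjusted p = 0.0911 with an estimated correlation), with Rps2 at -0.78, and 1, Rpl4, rose. Ribosome biogenesis genes fell in 19 of 27 (0 higher and 21 lower adjusted over the list alone; adjusted p = 0.0911 with an estimated correlation), with Myc at -1.34 and Npm1 at -0.50.

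The remaining lists did not pass camera in cluster 0. Adhesion and homing genes split into 6 higher, including L-selectin (Sell, 1.15), Cd47 (0.82) and Cd44 (0.71), and 4 lower (Cd34, Cd9, Cd63 and Itga6) of 17, with 6 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.15). In the Bcor complex list, 1 of 10 genes passed, Bcl6 (log2 fold change -0.74, SE 0.27, adjusted p = 0.0459, lower in 5 of 6 plates), and 0 adjusted over the list alone, and this call was lost without plate 1, 5 or 6. Bcor was higher in 5 of 6 plates without passing (log2 fold change 0.57, SE 0.21, adjusted p = 0.0518), at 59.3 ± 32.2 against 40.4 ± 19.5 CPM (SD, n = 6 plates). It passed without plate 2, with RLE scaling and at resolution 0.6. One stem cell factor of 11 rose, Hoxa5 (1.32), and in the megakaryocyte-erythroid list of 7, Mef2c rose and Lyl1 fell (-1.17), with the same counts adjusted over the list alone. Of 14 immediate early genes, Btg2 (1.09) and Jund rose and 6 fell. Mitochondrially encoded transcripts rose in 4 of 13, with mt-Nd5 at 0.31, and nuclear oxidative phosphorylation genes fell in 6 of 33, with Cycs at -0.79, and 1, Cox4i1, rose. These last 3 lists had 2 higher and 6 lower adjusted over the list alone, 4 higher and 0 lower adjusted over the list alone and 1 higher and 6 lower adjusted over the list alone.

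In total, edgeR's quasi-likelihood test called 1237 of 5021 genes, 532 higher and 705 lower, in cluster 0 over 6 plates. The 36 named genes that passed had an SE of at most 0.39 and an adjusted p of at most 0.0459. Of these, 33 changed the same way in every plate, which the rule for naming required of the genes with the largest changes. The count was 476 without the plate block, where Cd74, H2-Aa, H2-Ab1, Myc and other named genes that fell were no longer called, and 535 after thinning. It was 547 and 715 under the looser and stricter well limits and 722 at resolution 1.5, each over the 3 plates in which the matched cluster kept at least 10 cells. Foxo1 lost its call without plate 3, 4 or 6. The share of cluster 0 and the Siglech level were highest in plates 5 and 6, and without these plates 906 genes were called.

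**Figure D3:**
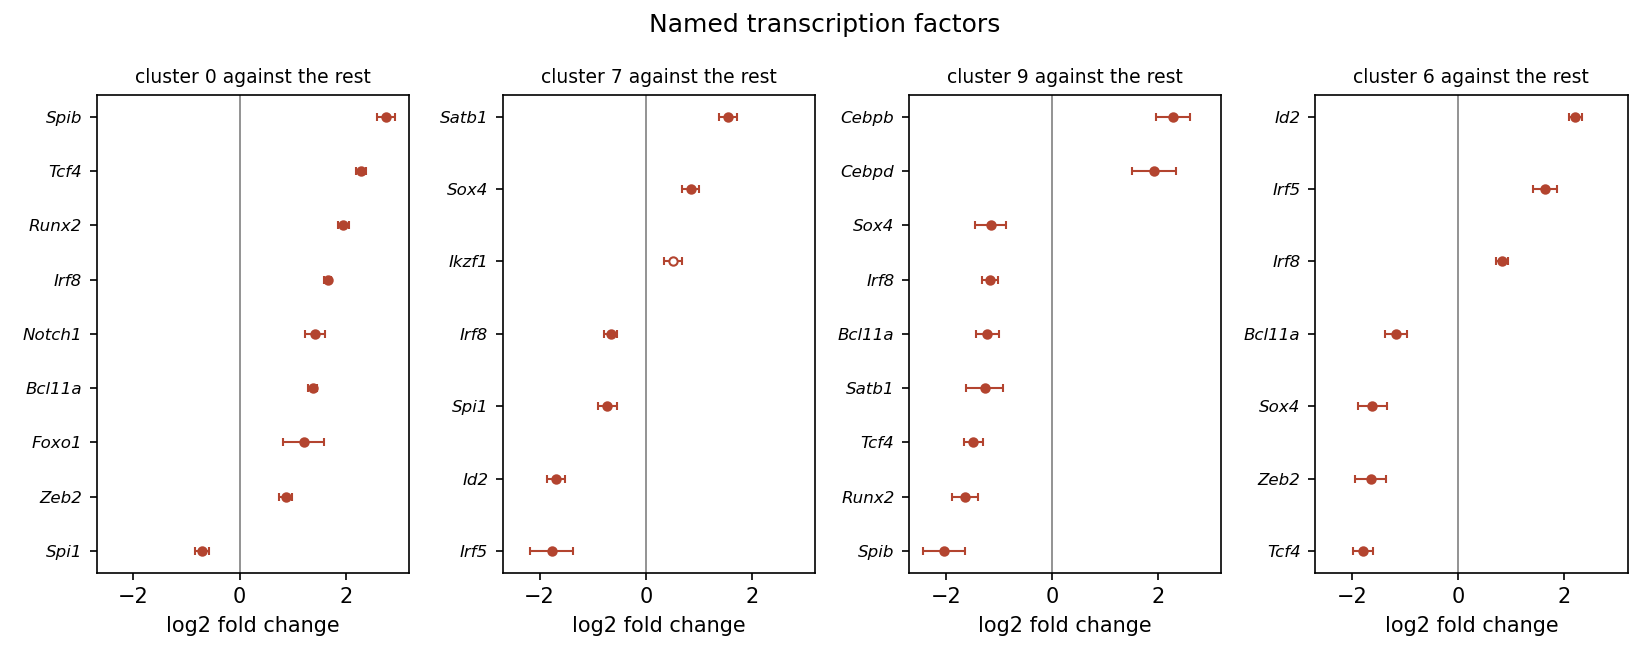
Points give the log2 fold change of the named transcription factors in clusters 0, 7, 9 and 6, each against the other cells of the same plates, with bars of 1 SE and open points where the adjusted p was 0.05 or more. Tcf4 was higher by 2.29 in cluster 0 and lower in clusters 9 (-1.48) and 6 (-1.80), and Satb1 was higher by 1.55 in cluster 7.

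Cluster 7 combined lymphoid factors with low antigen presentation. Satb1, a chromatin organiser of lymphoid progenitors (ENSMUSG00000023927, chromosome 17, 51736187 to 51833290, minus strand), stood at 379 ± 39.2 against 126 ± 37 CPM (SD, n = 5 plates; log2 fold change 1.55, SE 0.16, adjusted p = 5.73e-14), higher in 5 of 5. Sox4, a factor needed for early B and T cell development, was higher by 0.84 and Ikzf1 (Ikaros) by 0.52 without passing (adjusted p = 0.103, higher in 4 of 5 plates), though it passed with RLE scaling, on centred values and without plate 5. Satb1 and Sox4 were the 2 of 8 lymphoid factors that passed, and 3 passed adjusted over the list alone (camera adjusted p = 4.44e-08, and adjusted p = 0.064 with an estimated correlation). The T cell kinase Lck rose by 2.08, the sialyltransferase St6gal1 by 2.02, Myl4 by 2.42, Nrgn by 1.95 and the early activation antigen Cd69 by 1.64. The integrin Itga4 rose by 1.15, the RNA-binding stem cell regulator Msi2 by 1.02 and Mef2c, a factor of lymphoid commitment, by 0.81.

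MHC class II genes were lower in cluster 7 in 9 of 12, with Cd74 at -1.72, H2-Aa at -1.30 and H2-Ab1 at -1.06, and 10 were lower adjusted over the list alone (camera adjusted p = 1.22e-26, and adjusted p = 0.123 with an estimated correlation). Dendritic cell fate factors fell in 3 of 15, namely Id2 (-1.69), Irf8 (-0.66) and Spi1 (-0.72), and in 4 adjusted over the list alone (camera adjusted p = 0.000212, and adjusted p = 0.492 with an estimated correlation). Myeloid factors fell in 3 of 10, which adds Irf5 (-1.78), and in 5 adjusted over the list alone (camera adjusted p = 0.000357, and adjusted p = 0.123 with an estimated correlation). The receptor beta chains Csf2rb and Csf2rb2 fell by 1.61 and 2.15, the only passing cytokine receptors of 21 (camera adjusted p = 0.0529). G2/M genes fell in 4 of 52, namely Cdk1, Kif23, Top2a (-0.71) and Kif11 (-1.37), and in 7 adjusted over the list alone (camera adjusted p = 1.74e-07, and adjusted p = 0.123 with an estimated correlation). The tetraspanin Cd63 (-1.39) and Ifi27l2a (-0.69) were lower too. Bcor stood at 70.1 ± 50.6 against 47.3 ± 15.8 CPM (SD, n = 5 plates; adjusted p = 0.885, higher in 3 of 5).

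The test called 110 of 5105 genes, 30 higher and 80 lower, in cluster 7, and 58 without the plate block, where Irf8, Spi1, Sox4, Irf5, Top2a, Kif11 and Ifi27l2a were no longer called. The 23 named genes that passed had an SE of at most 0.44 and an adjusted p of at most 0.0166. DESeq2 called 37 higher and 45 lower, and the calls of Spi1 and Kif11 were lost without plate 3 or 4 and those of Irf5 and Cd63 without plate 3.

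Cebpb and Ccl6 were high in cluster 9. Cebpb, a factor of myeloid differentiation (ENSMUSG00000056501, chromosome 2, 167688915 to 167690418, plus strand), stood at 186 ± 87.3 against 35.9 ± 6.87 CPM (SD, n = 4 plates; log2 fold change 2.28, SE 0.32, adjusted p = 6.01e-07), higher in 4 of 4. The chemokine Ccl6 rose by 3.94, Gda by 4.17 and the fungal receptor Clec7a by 3.28. Of 10 myeloid factors, 4 rose, Cebpb, Cebpd (1.93, higher in 3 of 4 plates), Klf4 and Zeb2, and 1, Irf8, fell, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.71e-06, and adjusted p = 0.308 with an estimated correlation). Cytokine receptors rose in 4 of 21, Csf2ra (1.57), Csf2rb, Cxcr4 (1.08) and Tnfrsf1b (1.49), with 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00267, and adjusted p = 0.308 with an estimated correlation). The progenitor antigen Cd34 rose by 1.56 and the cathepsin Ctss by 0.94. In the interferon list, 1 of 26 passed, Ifit1 (1.79, higher in 3 of 4 plates), and 9 adjusted over the list alone (camera adjusted p = 2.63e-07, and adjusted p = 0.308 with an estimated correlation).

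Spib, Runx2 and Tcf4 were lower in cluster 9. Of 17 dendritic cell fate factors, 7 fell, including Spib (-2.03), Runx2 (-1.64), Tcf4 (-1.48), Bcl11a (-1.22) and Irf8 (-1.17), and Zeb2 and Klf4 rose, with 3 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.00157, and adjusted p = 0.428 with an estimated correlation). Among 8 lymphoid factors, Satb1 (-1.27), Sox4 (-1.16) and Bcl11a fell, and 4 fell adjusted over the list alone (camera adjusted p = 0.00561, and adjusted p = 0.308 with an estimated correlation). MHC class II genes fell in 5 of 12, with 1 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.579 with an estimated correlation). Cd74 had a log2 fold change of -0.61 (lower in 2 of 4 plates) and H2-Aa of -0.57 (lower in 3 of 4). Both calls were lost without plate 5, that of Cd74 also without plate 1, and without plates 5 and 6 the value of Cd74 was 0.12. Cd7 and Ccr7 fell by 3.68 and 2.50. Bcor stood at 0.11 (adjusted p = 0.962, higher in 3 of 4 plates). The neutrophil markers that named this cluster were also seen in wells outside it, at 0.0247, 0.4, 1.14, 0.498, 3.33 and 5.38 UMIs per well in plates 1 to 6.

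The test called 143 of 4949 genes, 95 higher and 48 lower, in cluster 9 over plates 1, 2, 5 and 6, which had at least 10 such cells. The 22 named genes that passed had an SE of at most 0.51 and an adjusted p of at most 0.0266. The other lists past the preset test alone were adhesion genes (2 higher and 0 lower of 18, 5 and 1 adjusted over the list alone), ribosomal protein genes (0 higher and 0 lower of 37, 0 and 0 adjusted over the list alone) and ribosome biogenesis genes (0 higher and 1 lower of 27, 0 and 1 adjusted over the list alone). These had an adjusted p of at most 0.0311, and of at least 0.308 with an estimated correlation. RLE scaling gave 113 higher and 34 lower and DESeq2 111 and 18, and the median over all genes was -0.15, so small falls are uncertain. The count was 72 without plate 6, 30 without plates 5 and 6, 33 without the plate block and 69 after thinning, and the calls of Cd34, Sox4, Satb1, Cebpd, Tnfrsf1b, Cxcr4, Ifit1 and Spib were each lost on leaving out 1 plate or more.

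The direct comparison of clusters 0 and 6 set the cells with Siglech and Pacsin1 among their top genes against those with Xcr1, Naaa and Itgae. Tcf4 stood at 1859.5 ± 397 CPM in cluster 0 and 169 ± 41.2 CPM in cluster 6 (SD, n = 5 plates; log2 fold change 3.45, SE 0.16, adjusted p = 5.53e-13), higher in 5 of 5 plates. Id2, the inhibitor of E proteins (ENSMUSG00000020644, chromosome 12, 25093799 to 25097140, minus strand), stood at 261 ± 81.8 CPM in cluster 0 and 2032.5 ± 512.5 CPM in cluster 6 (log2 fold change -3.07, SE 0.19, adjusted p = 2.31e-11), lower in 5 of 5. Of 12 dendritic cell fate factors, 6 were higher in cluster 0, including Spib (3.51), Runx2 (2.88), Zeb2 (2.37), Bcl11a (2.33) and Irf8 (0.60), and Id2 and Spi1 (-1.12) were lower, with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 1.31e-05, and adjusted p = 0.0984 with an estimated correlation). Lymphoid factors were higher in 4 of 5, Satb1, Sox4, Bcl11a and Notch1 (2.35), and in 5 adjusted over the list alone (camera adjusted p = 0.000368, and adjusted p = 0.239 with an estimated correlation). Pacsin1 (3.93), Blnk (3.76), Cd7 (3.63), Sell (2.69), Cd47 (1.11) and Ifnar2 (1.14) were higher in cluster 0 as well.

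Genes lower in cluster 0 than in cluster 6 included MHC class II genes, 9 of 12 with the same count adjusted over the list alone, such as Cd74 (-2.46) and H2-Aa (-2.34) (camera adjusted p = 2.48e-16, and adjusted p = 0.0984 with an estimated correlation). Naaa (-4.19), a lysosomal amidase, the integrin Itgae (-3.60), the homeodomain factor Pbx1 (-3.00), Cd9 (-2.13) and the repressor Bcl6 (-2.08) were lower too. Ifngr1, the interferon gamma receptor, was at -2.71 and the GM-CSF receptor chain Csf2ra at -1.53. Ribosomal protein genes were lower in 20 of 37, with Rplp1 at -0.63, and in 26 adjusted over the list alone (camera adjusted p = 3.98e-07, and adjusted p = 0.2 with an estimated correlation). The test called 504 of 2081 genes, 231 higher and 273 lower, and the 25 named ones had an SE of at most 0.47 and an adjusted p of at most 0.000787. One more list passed with the preset correlation alone, mitochondrial transcripts (4 higher and 0 lower of 11, 4 and 0 adjusted over the list alone). It had an adjusted p of at most 0.0457, and of at least 0.672 with an estimated correlation. The count was 231 without the plate block, 174 after thinning and 175 without plates 5 and 6, where Ifnar2 lost its call.

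Against all other cells, cluster 6, which the marker lists left unnamed, was high in Naaa and Itgae. Naaa (ENSMUSG00000029413, chromosome 5, 92257659 to 92278170, minus strand) stood at 1051 ± 264 against 65 ± 35.3 CPM (SD, n = 5 plates; log2 fold change 4.19, SE 0.17, adjusted p = 1.42e-133), higher in 5 of 5 plates. Hepacam2 rose by 5.58, Itgae by 4.27, Pbx1 by 3.09 and Id2 by 2.21. Irf8 (0.83), Id2, Batf3, Zbtb46 and Spi1 were the 5 of 17 fate factors that rose, and 6 fell, including Tcf4 (-1.80), Zeb2 (-1.65) and Bcl11a (-1.17), with 6 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.681). MHC class II genes rose in 8 of 12, with Cd74 at 1.95 and H2-Ab1 at 1.94, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.27e-28, and adjusted p = 0.133 with an estimated correlation). Irf5 (1.64), Ifngr1 (1.90), Csf2ra (1.52), Bcl6 (1.79) and Fos (1.82) rose. The lymphoid factors Sox4 (-1.61), Satb1 and Bcl11a fell, 3 of 7, and 4 fell adjusted over the list alone (camera adjusted p = 0.000528, and adjusted p = 0.262 with an estimated correlation). Sell and Ccr7 fell by 1.71 and 2.49, and Bcor stood at -0.01 (adjusted p = 0.997, lower in 4 of 5 plates). Also past the preset test alone were cytokine receptors (3 higher and 3 lower of 20, 5 and 3 adjusted over the list alone), ribosomal protein genes (3 higher and 0 lower of 37, 3 and 0 adjusted over the list alone), G2/M genes (0 higher and 5 lower of 51, 0 and 8 adjusted over the list alone), immediate early genes (4 higher and 1 lower of 16, 6 and 1 adjusted over the list alone) and interferon response genes (3 higher and 1 lower of 25, 6 and 2 adjusted over the list alone). Camera here gave an adjusted p of at most 0.0474, and of at least 0.268 with an estimated correlation. The test called 302 of 4975 genes, 187 higher and 115 lower, and the named genes that passed had an SE of at most 0.62 and an adjusted p of at most 0.00144. The count was 181 without the plate block, 189 after thinning, 181 without plate 5 and 169 without plates 5 and 6. Without both plates, Ccr7, Bcl6, Bcl11a, Zeb2 and Fos were no longer called.

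Cluster 5, which the marker lists left unnamed, was high in Ccr7 and Ccl22. Ccr7, the receptor that guides dendritic cells to lymph nodes (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077, minus strand), stood at 2267 ± 919.5 against 50.5 ± 19.5 CPM (SD, n = 4 plates; log2 fold change 5.56, SE 0.19, adjusted p = 8.2e-32), higher in 4 of 4 plates. The chemokine Ccl22 rose by 5.59, the NF-κB subunit Relb by 4.58, Gbp2 by 4.27, Cd63 by 3.16 and Stat3 by 1.47. Dendritic cell fate factors rose in 6 and fell in 4 of 19, with 6 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.0251, and adjusted p = 0.436 with an estimated correlation). MHC class II presentation genes rose in 9 of 12, the same number adjusted over the list alone, with Ifi30 at 2.78 and Cd74 at 1.72 (camera adjusted p = 3.71e-10, and adjusted p = 0.436 with an estimated correlation). Immediate early genes rose in 6 of 16, the same number adjusted over the list alone, among them Klf6 (2.99) and Nfkbia (1.99) (camera adjusted p = 1.56e-06, and adjusted p = 0.191 with an estimated correlation). In the Bcor complex list, Kdm2b (1.16) and Bcl6 (1.94) were the 2 of 9 that rose, also adjusted over the list alone (camera adjusted p = 0.377), and Bcor stood at 0.60 (adjusted p = 0.391, higher in 2 of 4 plates). Tcf7, better known from T cells, rose by 4.33 and Csf2rb by 2.16. Irf8 was at -0.73, Nme1 at -1.45 and Rps18 at -0.99, one of 18 of 37 ribosomal protein genes that fell, 22 adjusted over the list alone (camera adjusted p = 8.54e-05, and adjusted p = 0.436 with an estimated correlation). Past the preset test alone were also cytokine receptors (8 higher and 1 lower of 22, 11 and 1 adjusted over the list alone), G2/M genes (0 higher and 11 lower of 49, 0 and 12 adjusted over the list alone), interferon response genes (5 higher and 2 lower of 26, 6 and 3 adjusted over the list alone), ribosome biogenesis genes (0 higher and 8 lower of 27, 0 and 11 adjusted over the list alone) and S phase genes (0 higher and 8 lower of 42, 0 and 10 adjusted over the list alone). For these camera gave an adjusted p of at most 0.0099, and of at least 0.436 with an estimated correlation. The test called 673 of 5023 genes, 388 higher and 285 lower, and the named genes that passed had an SE of at most 0.51 and an adjusted p of at most 0.00616. The count was 408 without the plate block and 291 after thinning. The median over all genes was -0.17, DESeq2 gave 386 higher and 175 lower, and Kdm2b lost its call without plate 3 or 6.

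Cluster 1 was high in MHC class II genes, all 12 of which rose, also adjusted over the list alone (camera adjusted p = 7.61e-26, and adjusted p = 0.198 with an estimated correlation). Ciita, the transactivator of these genes (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418, plus strand), stood at 346 ± 77.8 against 135 ± 129 CPM (SD, n = 5 plates; log2 fold change 1.78, SE 0.18, adjusted p = 3.89e-08), higher in 5 of 5 plates, and Cd74 rose by 1.41 (higher in 4 of 5). The other cells differed in mix between plates, as in every comparison with the rest. Clusters 2 and 3, low in MHC class II genes, took 25.7 and 15.1% of plate 2 and 1.19 and 4.46% of plate 6. Clusters 4, 5 and 6, high in them, took 0.592, 0.888 and 2.96% of plate 2 and 25.6, 9.23 and 11% of plate 6. The size of the rise therefore depends on that mix. Fate factors rose in 5 of 19, Id2 (1.69), Klf4 (1.56), Cbfa2t3 (0.90), Spi1 (0.70) and Irf4, and Tcf4 fell, with 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 2.98e-05, and adjusted p = 0.246 with an estimated correlation). Interferon response genes rose in 8 of 25, and 11 rose adjusted over the list alone (camera adjusted p = 7.74e-09, and adjusted p = 0.266 with an estimated correlation). Kit rose by 1.08 and the integrin Itgb7 by 1.14. G2/M genes fell in 8 of 52, with Top2a at -0.55, and in 17 adjusted over the list alone (camera adjusted p = 1.06e-10, and adjusted p = 0.246 with an estimated correlation). Sox4 fell by 0.67, a call that was lost without plate 1 or 3. Irf8 (-0.26, adjusted p = 0.189, lower in 4 of 5 plates) and Bcor (-0.18, adjusted p = 0.76, lower in 3 of 5) did not pass. Irf8 passed with no low-count filter, at resolution 0.6, on centred values and under the stricter well limits.

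The test called 305 of 5450 genes, 194 higher and 111 lower, in cluster 1, and the named genes that passed had an SE of at most 0.25 and an adjusted p of at most 0.00143. Further lists past the preset test alone were cytokine receptors (5 higher and 1 lower of 21, 9 and 2 adjusted over the list alone), immediate early genes (2 higher and 1 lower of 15, 5 and 1 adjusted over the list alone), mitochondrial transcripts (0 higher and 2 lower of 13, 0 and 3 adjusted over the list alone), myeloid factors (2 higher and 0 lower of 12, 2 and 0 adjusted over the list alone), oxidative phosphorylation genes (0 higher and 0 lower of 33, 0 and 0 adjusted over the list alone), ribosome biogenesis genes (0 higher and 5 lower of 27, 0 and 12 adjusted over the list alone) and S phase genes (0 higher and 5 lower of 42, 0 and 10 adjusted over the list alone). For these lists camera gave an adjusted p of at most 0.0335, and of at least 0.159 with an estimated correlation. Plate 6 held 12 cells of cluster 1, and the count was 749 without plate 6 and 96, 155, 84 and 111 without plate 1, 2, 3 or 4. It was 6 without the plate block, 601 at resolution 0.6, 791 on centred values and 694 under the stricter well limits.

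Cluster 2 was high in ribosome biogenesis genes and low in MHC class II genes. Myc, the growth-promoting factor (ENSMUSG00000022346, chromosome 15, 61985391 to 61990374, plus strand), stood at 254 ± 40 against 143 ± 8.75 CPM (SD, n = 4 plates; log2 fold change 0.81, SE 0.09, adjusted p = 5.7e-12), higher in 4 of 4 plates. Ribosome biogenesis genes rose in 21 of 27, with Npm1 at 0.39 and Ncl at 0.33, and in 24 adjusted over the list alone (camera adjusted p = 1.12e-16, and adjusted p = 0.0334 with an estimated correlation). Ribosomal protein genes rose in 21 of 37 and in 26 adjusted over the list alone (adjusted p = 0.0459 with an estimated correlation). The progenitor antigen Cd34 rose by 0.71, the uracil glycosylase Ung by 0.96 and Sox4 by 0.33. All 12 MHC class II genes fell, also adjusted over the list alone, with Cd74 at -2.09 (camera adjusted p = 1.07e-67, and adjusted p = 0.0318 with an estimated correlation). Interferon response genes fell in 16 of 24, such as Ly6a (-0.97), and 1, Ifi27, rose, with 1 higher and 19 lower adjusted over the list alone (adjusted p = 0.0375 with an estimated correlation). Cytokine receptors fell in 9 of 21 and in 10 adjusted over the list alone (adjusted p = 0.0459 with an estimated correlation), with Csf2ra at -1.33. Fate factors fell in 11 of 17, with Id2 at -1.76 and Irf8 at -0.36, and in 12 adjusted over the list alone (camera adjusted p = 3.96e-13, and adjusted p = 0.0748 with an estimated correlation). Bcl6 (-1.22) and Top2a (-0.62) fell, and Bcor stood at -0.02 (adjusted p = 0.945, lower in 2 of 4 plates).

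The test called 893 of 5448 genes, 432 higher and 461 lower, in cluster 2, and the named genes that passed had an SE of at most 0.26 and an adjusted p of at most 0.000504. Others that passed with the preset correlation alone were adhesion genes (2 higher and 7 lower of 18, 2 and 9 adjusted over the list alone), G2/M genes (2 higher and 22 lower of 52, 3 and 28 adjusted over the list alone), mitochondrial transcripts (6 higher and 0 lower of 13, 8 and 0 adjusted over the list alone), myeloid factors (0 higher and 5 lower of 10, 0 and 5 adjusted over the list alone), oxidative phosphorylation genes (6 higher and 0 lower of 33, 7 and 0 adjusted over the list alone) and S phase genes (9 higher and 2 lower of 42, 11 and 2 adjusted over the list alone). Camera gave these an adjusted p of at most 0.0138, and of at least 0.0815 with an estimated correlation. DESeq2 called 435, and the count was 464 without plate 4, 187 without the plate block and 511 after thinning.

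Cluster 3 was high in genes of the cell cycle. Top2a (ENSMUSG00000020914, chromosome 11, 98992943 to 99024189, minus strand) stood at 756.5 ± 122.5 against 346 ± 131 CPM (SD, n = 6 plates; log2 fold change 1.17, SE 0.10, adjusted p = 1.25e-08), higher in 6 of 6 plates. G2/M genes rose in 45 of 52, including the proliferation antigen Mki67 (1.02) and Hmgb2 (0.93), and in 47 adjusted over the list alone (camera adjusted p = 5.22e-30, and adjusted p = 0.0139 with an estimated correlation). S phase genes rose in 18 of 42, with Tyms, which makes thymidylate, at 1.26, with 23 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.79e-09, and adjusted p = 0.2 with an estimated correlation). All 12 MHC class II genes fell, also adjusted over the list alone, with Cd74 at -2.69 (camera adjusted p = 7.24e-40, and adjusted p = 0.00245 with an estimated correlation). Fate factors fell in 14 of 16, the same number adjusted over the list alone, with Id2 at -2.16, Klf4 at -1.93 and Irf8 at -0.55 (adjusted p = 0.00281 with an estimated correlation). Interferon response genes fell in 19 of 24 and 1, Ifi27, rose, with 1 higher and 21 lower adjusted over the list alone (adjusted p = 0.00245 with an estimated correlation). Cytokine receptors fell in 12 of 21, Csf2rb among them, and Il1r1 and Cxcr4 rose, with 3 higher and 15 lower adjusted over the list alone (adjusted p = 0.0472 with an estimated correlation). Immediate early genes fell in 7 of 14 and rose in 1, with 3 higher and 9 lower adjusted over the list alone (adjusted p = 0.0383 with an estimated correlation). Bcor stood at -0.22 (adjusted p = 0.477, lower in 5 of 6 plates). Other lists that passed only with the preset correlation were adhesion genes (2 higher and 7 lower of 18, 2 and 8 adjusted over the list alone), ribosomal protein genes (13 higher and 0 lower of 37, 19 and 1 adjusted over the list alone), myeloid factors (0 higher and 4 lower of 10, 0 and 4 adjusted over the list alone), oxidative phosphorylation genes (5 higher and 0 lower of 33, 5 and 0 adjusted over the list alone) and ribosome biogenesis genes (12 higher and 0 lower of 27, 18 and 0 adjusted over the list alone). These lists had an adjusted p of at most 0.0179, and of at least 0.0862 with an estimated correlation. The test called 1102 of 5358 genes, 509 higher and 593 lower, and the named genes that passed had an SE of at most 0.24 and an adjusted p of at most 5.34e-05. The count was 530 without the plate block, 679 on centred values and 543 after thinning.

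Cluster 4 joined MHC class II genes with Itgam and Clec10a. Its separation from cluster 1 depends on the clustering. On centred values and at resolution 0.6 its largest overlap, 0.271 and 0.286, was with the cluster matched to cluster 1. Cells of each of these clusters were part of the rest for the other, so the comparisons do not show them to be distinct classes. Itgam, which encodes CD11b (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491, plus strand), stood at 233 ± 33.3 against 52.8 ± 44 CPM (SD, n = 3 plates; log2 fold change 2.25, SE 0.27, adjusted p = 4.3e-11), higher in 3 of 3 plates. The lectin Clec10a rose by 2.46 and Jun by 1.97. All 12 MHC class II genes rose, also adjusted over the list alone, with Cd74 at 1.45 and H2-Aa at 1.28 (camera adjusted p = 1.14e-56, and adjusted p = 0.173 with an estimated correlation). Fate factors rose in 5 of 19, Klf4 (1.23), Cbfa2t3 (1.18), Spi1 (0.91), Id2 and Irf4, and fell in 4, Irf8 (-1.56), Tcf4, Spib and Runx2, with 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.395). Kit rose by 1.38, and Ccr7 (-2.20) and Sell (-0.96) fell. G2/M genes fell in 7 of 50, with Hmgb2 at -1.31, and in 28 adjusted over the list alone (camera adjusted p = 3.48e-17, and adjusted p = 0.173 with an estimated correlation). Bcor stood at -0.71 (adjusted p = 0.782, lower in 2 of 3 plates). Also passing with the preset correlation alone were cytokine receptors (2 higher and 1 lower of 23, 2 and 1 adjusted over the list alone), ribosomal protein genes (0 higher and 0 lower of 37, 0 and 0 adjusted over the list alone), immediate early genes (1 higher and 0 lower of 16, 3 and 1 adjusted over the list alone), interferon response genes (4 higher and 0 lower of 26, 4 and 0 adjusted over the list alone) and S phase genes (0 higher and 1 lower of 42, 0 and 4 adjusted over the list alone). All of these had an adjusted p of at most 0.0269, and of at least 0.207 with an estimated correlation. The test called 147 of 5248 genes, 74 higher and 73 lower, in plates 3, 5 and 6, and the named genes that passed had an SE of at most 0.31 and an adjusted p of at most 0.00808. The count was 43 without plate 5, 48 without plate 6, 13 without the plate block and 69 after thinning. DESeq2 gave 49 higher and 23 lower, without Clec10a, and the calls of Spi1, Kit and Sell were lost without plate 5 and those of Klf4 and Sell without plate 6.

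Cluster 8 joined cell cycle genes with the myeloid factors Klf4 and Spi1. Top2a stood at 834 ± 64.8 against 463 ± 175 CPM (SD, n = 4 plates; log2 fold change 0.89, SE 0.12, adjusted p = 9.25e-10), higher in 4 of 4 plates. G2/M genes rose in 12 of 52, with the kinesin Kif23 at 1.11, and in 21 adjusted over the list alone (camera adjusted p = 3.59e-25, and adjusted p = 0.107 with an estimated correlation). The cell cycle factors E2f2 and E2f8 rose by 1.49 and 1.18. Klf4 (1.27), Id2 (1.05), Spi1 (0.62) and the selectin ligand Selplg (0.55) rose. Lymphoid factors fell in 3 of 8, Sox4 (-1.20), Satb1 (-1.06) and Notch1, and in 4 adjusted over the list alone (camera adjusted p = 1.77e-06, and adjusted p = 0.107 with an estimated correlation). Tcf4 fell by 0.98, and Bcor stood at -0.12 (adjusted p = 0.968, lower in 3 of 4 plates). More lists past the preset test alone were ribosomal protein genes (0 higher and 0 lower of 37, 0 and 0 adjusted over the list alone), MHC class II genes (1 higher and 0 lower of 12, 3 and 0 adjusted over the list alone), mitochondrial transcripts (0 higher and 0 lower of 13, 0 and 0 adjusted over the list alone), myeloid factors (3 higher and 0 lower of 10, 3 and 0 adjusted over the list alone), ribosome biogenesis genes (0 higher and 0 lower of 27, 0 and 0 adjusted over the list alone) and S phase genes (4 higher and 1 lower of 42, 7 and 1 adjusted over the list alone). Each of these had an adjusted p of at most 0.0331, and of at least 0.278 with an estimated correlation. The test called 109 of 5093 genes, 76 higher and 33 lower, and the named genes that passed had an SE of at most 0.31 and an adjusted p of at most 0.00201. The count was 42, 46 and 51 without plate 1, 2 or 4, 5 without the plate block, 218 on centred values and 38 after thinning. DESeq2 gave 62 higher and 14 lower, no low-count filter 68 and the looser well limits 65, and the calls of E2f2, E2f8, Klf4, Spi1, Satb1 and Selplg were each lost without 1 of these plates or more.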

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

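Mpo, the myeloperoxidase gene of early granulocytes and monocytes, stood at 236 CPM in plate 5, far from the other 5 plates, the nearest of which had 105. The gap was 0.803 of the whole range. Of 40 groups of plate values tested in this way, 1 stood out, and chance alone marks about 1 in 20 groups.

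The wells left out by the quality limits, which entered no comparison of clusters, held 55409 UMIs over all plates, a signal above the limit that a count of 0 allows. This was 0.292, 0.269, 0.248, 0.25, 0.323 and 0.405% of the UMIs of plates 1 to 6. The median per left-out well was 88, 245, 114, 195, 124 and 178 UMIs.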

How the results depend on the processing

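The comparisons of the unnamed clusters, that of cluster 0 with cluster 6, and the alternative without plates 5 and 6 were chosen after the data were seen. Genes called were 1237 in cluster 0, 305 in cluster 1, 893 in cluster 2, 1102 in cluster 3, 147 in cluster 4, 673 in cluster 5, 302 in cluster 6, 110 in cluster 7, 109 in cluster 8, 143 in cluster 9 and 504 in cluster 0 against cluster 6. RLE size factors kept every one of these counts within 1.5 times. Where an alternative moved a count by more than that, its value follows, and the cause was not tested unless stated. Without the replicate block it was 476 in cluster 0, 6 in cluster 1, 187 in cluster 2, 530 in cluster 3, 13 in cluster 4, 408 in cluster 5, 181 in cluster 6, 58 in cluster 7, 5 in cluster 8, 33 in cluster 9 and 231 in cluster 0 against cluster 6, as this fit leaves the differences between plates in its error. With cells thinned it was 535 in cluster 0, 511 in cluster 2, 543 in cluster 3, 69 in cluster 4, 291 in cluster 5, 189 in cluster 6, 38 in cluster 8, 69 in cluster 9 and 174 in cluster 0 against cluster 6, a setting with fewer UMIs and cells. DESeq2 called 435 in cluster 2 and 72 in cluster 4. Resolution 1.5 gave 722 in cluster 0, over 3 of its 6 plates, and resolution 0.6 601 in cluster 1. At least 500 UMIs and 250 genes gave 547 in cluster 0 and 65 in cluster 8, and at least 2000 UMIs and 1000 genes 715 in cluster 0 and 694 in cluster 1, over fewer plates than before, as the matched clusters had under 10 cells in the others. Values centred within each plate gave 791 in cluster 1, 679 in cluster 3 and 218 in cluster 8, and no low-count filter 68 in cluster 8. Without plates 5 and 6 it was 749 in cluster 1, 169 in cluster 6, 30 in cluster 9 and 175 in cluster 0 against cluster 6, with fewer plates. Leaving out 1 plate at a time gave 84 to 749 in cluster 1, 464 to 784 in cluster 2, 43 to 188 in cluster 4, 181 to 267 in cluster 6, 42 to 115 in cluster 8 and 72 to 118 in cluster 9. It stayed within 1.5 times at 966 to 1132 in cluster 0, 788 to 1058 in cluster 3, 474 to 606 in cluster 5, 82 to 103 in cluster 7 and 352 to 518 in cluster 0 against cluster 6. The named genes gave 2957 values under alternatives. Of these, 2724 kept direction and side of the threshold, 206 lost the call, 11 gained one and 16 changed sign. Of those that changed sign, 0 passed the threshold the other way. Of 210 named genes and comparisons, 198 passed in the original fit. Many were named for passing with the same direction in every plate, so this stability is partly built in. The log2 fold change of Bcor, cluster 1 against the rest, was 0.15 at resolution 1.5 and 0.0126 with at least 2000 UMIs. The log2 fold change of Bcor, cluster 2 against the rest, was 0.0525 on centred values and -0.10 to 0.0783 without 1 plate. The log2 fold change of Bcor, cluster 6 against the rest, was 0.0112 with RLE, 0.00860 with DESeq2, 0.0200 at resolution 1.5 and -0.33 to 0.0990 without 1 plate. The log2 fold change of Bcor, cluster 8 against the rest, was 0.21 with cells thinned. The log2 fold change of Bcor, cluster 9 against the rest, was -0.0147 with no replicate block, -0.0450 with no low-count filter and -0.60 with cells thinned. The log2 fold change of Cd74, cluster 9 against the rest, was 0.12 without plates 5 and 6. With an estimated correlation, 0 gene lists passed camera in clusters 0, 1, 4, 5, 6, 7, 8 and 9 and in cluster 0 against cluster 6, where 9, 11, 7, 9, 7, 5, 8, 9 and 5 passed with the preset one, and 5 of 12 held in cluster 2 and 6 of 12 in cluster 3.

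Under both other well limits, Bcor, Dach1 and Irf8 levels per plate stayed within the exact Poisson interval of the plate's original level (36 values). Of the shares of clusters by plate, 211 values lay within the exact Clopper-Pearson interval of the original share and 65 outside it. Cells kept were 2018, 2042 and 1973 under the 3 limits, in 11, 12 and 10 clusters, and there were 8 clusters at resolution 0.6, 15 at 1.5 and 11 on centred values. Some comparisons had no matching cluster in at least 3 plates and gave no value: clusters 4, 7 and 8 at resolution 0.6, cluster 4 on centred values, clusters 2, 4, 7 and 9 with at least 500 UMIs, and clusters 7 and 9 with at least 2000 UMIs. Without plates 5 and 6, cluster 4 had 1 plate and gave no value, and clusters 5 and 9 had 2 plates, with 609 genes called in cluster 5. Cluster 0 against cluster 6 was not run on other clusterings. The comparisons by Dach1 and of lymphoid-primed with myeloid-primed cells were not run, and neither were their other settings, among them another thinning depth and seed. The 12 Dach1 UMIs in all cannot separate expressing cells from others.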

Other observations

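The tests of the depth of the plates, for the share of cluster 0 and for the Bcor level, were chosen only after the result was seen, and so were the comparisons other than those of clusters 0, 7 and 9. The marker lists of cells outside the lineages described so far gathered few transcripts. Over all kept wells, the megakaryocyte markers summed to 11.1 CPM, the erythroid markers to 33.2, the B cell markers to 25.7 and the T and NK cell markers to 19.7. The T and NK list does not hold Gzmc and Xcl1, top genes of cluster 4 at 105 and 95.5 CPM there. The mast cell and basophil markers summed to 6.2, the eosinophil markers to 1.61 and the stromal and endothelial markers to 23.5 CPM. The lists of present lineages summed to 1439.5 for myeloid-primed, 1266 for lymphoid-primed, 1119 for monocyte-macrophage, 1084 for dendritic and 757 for neutrophil markers. The stem cell list came to 226, with 2 of its 11 measured genes at 10 CPM or more, and 14 UMIs of Procr, 38 of Hlf and 18 of Mecom in all.

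The levels of Kit, Cd34, Flt3 and Bcor are given by cluster over all plates together, which contribute unequal numbers of cells. Differences between clusters beyond the comparisons already made were not tested. Kit stood at 32.8, 68.8, 32.3, 23.2, 120.3, 120.0, 63.8, 29.4, 38.6 and 28.5 CPM in clusters 0 to 9. Cd34 stood at 31.9, 61.2, 117, 74.5, 37.2, 33.2, 34.3, 66.8, 85.6 and 146 in the same order. Flt3 stood at 208, 195.5, 186, 197, 178.5, 168, 212, 289.5, 145 and 90.5, and Bcor at 55.1, 43.4, 49, 42, 17.2, 59.3, 28.6, 58.7, 44.7 and 40.1. Cluster 10, with 5 wells, was not tested.

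Transcripts of the neutrophil markers occurred outside the neutrophil-like cluster, at 0.0247 UMIs per well in plate 1 and 5.38 in plate 6, in 2.16% and 95.5% of these wells. Exchange of barcoded molecules after pooling would reach left-out wells as well. These held at most 0.0814 times as many per well as the kept ones, with an upper bound of 0.223 in plate 3. Yet left-out wells had plate medians of 88 to 245 UMIs, against 5507 to 12414 in kept wells. If exchange follows the molecules that carry a well's barcode, a low ratio per well cannot decide the question, so exchange stays open. Free RNA in the sorted suspension would reach all clusters alike, at most 3 times apart by the limit set beforehand. The most and least affected clusters differed by 1.78, 1.92, 1.64 and 2.26 times in plates 2, 3, 5 and 6, within that limit, and by 3.09 times in plate 4 (95% interval 0.727 to 10.2). The upper bounds passed 3 in every one of these plates, the lowest at 3.25, so free RNA is not excluded and stays open. Both may contribute and cannot be told apart with these counts, and low expression in the cells themselves stays open too. In plate 5 the marker UMIs outside and inside cluster 9 had a like mix, with Ngp at 12.1 and 11.5% and Ltf at 2.54 and 2.05%. In plate 4 the mix differed, with Mmp8 at 18.8% outside and 3.77% inside, and in plate 2 at 10.8 and 4.35%. The mix therefore does not decide between spread from cluster 9 and expression in the cells. No biological explanation was tested.

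The share of cluster 0 was 8.88% in plate 2 and 34.9% in plate 5. The tables argue against depth as the whole cause. With cells of at least 2000 UMIs thinned to that depth and clustered again, the matched cluster took 3.07, 0.597, 6.34, 3.02, 35.8 and 33% of plates 1 to 6, a ratio of 59.9. Its overlap with cluster 0 was 0.626, and its share fell in plates 1 to 4 only, so it was a narrower group. The ratio rests on the small share of plate 2, and nothing is concluded from its size. A first thinning to 5000 UMIs gave no matching cluster. The tables argue against offsets between plates in the clustering too, as centring within each plate left 11.7, 8.88, 13.9, 12.8, 31 and 29.2%, a ratio of 3.5. Differences in sorting or in the mice stay open, and the labels give no batch, date or genotype by plate. No biological explanation was tested.

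The level of Bcor was highest in plate 1 and lowest in plate 6. The tables argue against cluster composition as the whole cause: the ratio of observed to expected Bcor UMIs, given each cluster's level over all plates, was 1.44, 0.841, 1.07, 1.31, 0.606 and 0.445, and the highest was 3.23 times the lowest (95% bootstrap interval 2.11 to 5.46). They argue against depth as well, since plates 1 and 6, whose median depths differed by 1.03 times, differed in Bcor by 3.74 times (95% interval 2.46 to 6.1). A difference in the mix of edited and unedited wells, if an edit lowers the 3′ count, or a batch effect stays open and could not be tested without labels. No biological explanation was tested.

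For each comparison, the sums were also divided into other groups of the same sizes, and the genes called by edgeR were counted for up to 100 divisions. The plate pairs the sums, so the real division is set against those that part the sums of every plate, as it does. In cluster 0, 1 of 32 such divisions, the real one, called its 1237 genes, with 9 in the highest other. In cluster 3, 1 of 32 called its 1102, with 0 in the highest other. The real division came from clustering these same cells, and no other division was clustered again. That it called the most genes therefore cannot decide whether chance formed the clusters, and no conclusion is drawn from it. In the other comparisons such divisions were too few for a share under 0.05. The real count and the highest other were 893 and 0 in cluster 2, 147 and 0 in cluster 4, 673 and 0 in cluster 5, 302 and 17 in cluster 6, 110 and 3 in cluster 7, 109 and 3 in cluster 8, 143 and 6 in cluster 9 and 504 and 0 in cluster 0 against cluster 6. In cluster 1, 2 of 16 called at least the real 305, and the other one, which swaps the sums of plate 6, called 530. That plate held 12 cells of cluster 1, and without it 749 genes were called. The remaining divisions differ from the real one in that they put both sums of at least 1 plate on the same side. With these included, 2 of 100 divisions reached the real count in cluster 1 and 1, the real one, in each other comparison, and the highest other was 557, 605, 169, 91 and 114 genes over 100 divisions in clusters 0, 3, 6 and 7 and in cluster 0 against cluster 6, 1, 0, 11 and 69 genes over 32 in clusters 2, 5, 8 and 9, and 0 over 10 in cluster 4.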
